A study of Homo sapiens with 12 samples.

How the data were processed

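Gene expression was measured by RNA sequencing in 2 human hepatocellular carcinoma cell lines, Huh7 and HCCLM3, each with an siRNA against circASH2 (si-circASH2) or a negative control siRNA (si-NC). Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a SMARTer mRNA kit. The siRNA sequences, the time after transfection and the strand of the libraries are not given in the sources used here. The 12 libraries were put into 4 groups of 3 by their labels. The values analysed were the deposited gene counts, which per the file headers are counts per gene for each library. The deposited FPKM of the same genes, per the file headers, were scaled by the authors for gene length and depth, and served only as an alternative. The aligner, the counting tool and the annotation are not given in the sources used here. The submitters' processing notes list the builds hg38, GRCm38 and mm10 without a role for each. All columns of both tables were used.

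The tables held 23583 features, of which 2206 were at 0 in all libraries and 3854 had only an assembled identifier starting with MSTRG. Total counts lay between 29006781 and 30858895 per library. Counts of 1 (1938 values) were rarer than counts of 2 (6826) or of 3 (4777), so the lowest counts do not follow whole single reads and were treated as uncertain. A level of 3 counts in 1 library was worth between 0.0972 and 0.103 CPM, and 3 counts over a group between 0.0328 and 0.0338 CPM. Replicates were compared in pairs, and the chi-square of their counts per degree of freedom lay between 3.76 and 8.06, so no pair was treated as 1 library deposited more than once. Histones, ribosomal proteins, metallothioneins and other genes with near-identical copies, and genes that overlap others on the opposite strand, are uncertain because how reads were shared is not known.

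Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr over the 4 groups (minimum count of 10), which left 16946 features, 2505 of them MSTRG. Libraries were scaled by TMM, 1 coefficient was fitted per group with the robust quasi-likelihood fit, 8 residual degrees of freedom and a common biological coefficient of variation of 5.65%, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. CPM are TMM scaled. The 5 comparisons were the knockdown in Huh7, the knockdown in HCCLM3, the average of both effects, their difference (HCCLM3 minus Huh7, the interaction) and the si-NC libraries of HCCLM3 against those of Huh7 (baseline). Standard errors were computed as the absolute log2 fold change divided by the square root of the F statistic. Overlap of calls was set beside the number that independent lists of the same sizes would share. This number takes every gene as equally likely to be called, so it is only a rough guide.

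Gene groups were 33 lists written from textbook knowledge before the data were examined, as were the comparisons, the tests and the alternatives. Lists with at least 5 tested members were tested with camera of limma 3.58.1 with a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Counts of list members were also made from p-values adjusted over the list alone. The lists covered actin cytoskeleton, focal adhesion, mesenchymal and epithelial genes, matrix proteases, targets of YAP, TGF-beta, Wnt and p53, secreted hepatocyte proteins, hepatocyte transcription factors, cholesterol and fatty acid synthesis, glycolysis, hypoxia, interferon, NF-kB, immediate early genes, ATF4, endoplasmic reticulum chaperones, heat shock, mitosis, DNA replication, histones, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, H3 lysine 4 methylation, partners of YBX1, and markers of fibroblasts, endothelium and leukocytes. No list test was made at baseline.

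The genes named in the text follow a rule set before the data were examined. For each knockdown comparison they are the 8 with the largest rise and the 8 with the largest fall among genes past the threshold with at least 5 CPM in the higher group and with no overlap between the libraries of the groups (not required for the interaction), and 5 in each direction at baseline. Genes without a symbol were passed over, and so were genes of the Y chromosome, an exclusion added after the data were seen. ASH2L, TPM1, TPM2, TPM3, TPM4 and YBX1 were named whatever their values, and up to 4 members with the smallest p stand for each list. This gave 188 genes, and some genes and 1 list that the rules cover are not reported here.

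Short sequences were searched in the 3′ UTRs of GENCODE 29 (GRCh38), where 14081 of 14441 tested named features (97.5%) were found and 10855 genes with at least 1 CPM had a 3′ UTR. Each of 16187 sequences of 7 bases was scored by comparing the fold changes of genes with and without it. Extreme fold changes were capped, and the part explained by length and base composition of the searched sequence was removed first. The values so adjusted were permuted 100 times for each line. Shares of carriers and medians of fold changes were not adjusted in this way. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used here. Coordinates are those of GRCh38 and count from 1.

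Alternatives were DESeq2 1.42.0 with its Wald test, DESeq2 size factors and upper quartile factors in edgeR, a fit without robust estimation, each line fitted alone, no filter on low counts, a filter of 5 CPM in 3 libraries, an absolute log2 fold change above 1, a block for the replicate number, leaving out each library in turn, and limma on log2 FPKM with a pseudocount of 1 or 0.1. Counting only genes with at least 1 CPM was added after the data were seen. The tests were also tested on simulated data, with fold changes planted in 50 genes for each size, and 50 of 50 genes with a 2-fold change were called in Huh7 and in HCCLM3. With a 1.25-fold change 41 of 50 genes were called in Huh7 and 36 of 50 in HCCLM3. The libraries of each comparison were also divided in other ways to count how often as many genes passed.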

Results

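RNA sequencing was used to measure gene expression in 2 human hepatocellular carcinoma cell lines after knockdown of circASH2, a circular RNA that takes its name from the gene ASH2L. Huh7 is a carcinoma line that keeps many hepatocyte functions, and HCCLM3 is a carcinoma line known for a high capacity to metastasise. Each line was given either an siRNA against circASH2 (si-circASH2) or a negative control siRNA (si-NC), and per the labels the purpose was to learn how loss of circASH2 affects metastasis. The 4 groups held 3 libraries each, 12 in all, with total counts between 29006781 and 30858895 per library. At this depth 3 counts in 1 library corresponded to between 0.0972 and 0.103 CPM, the count scaled to library size. No label says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Errors are the SD of 3 libraries beside a CPM and the standard error of the model beside a log2 fold change, with n = 3 per group throughout.

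The libraries of each group lay close together. The first principal component separated the lines and held 94.1% of the variance, the second held 1.28% and separated si-circASH2 from si-NC libraries in both lines, and the third held 0.909%. Mitochondrially encoded genes took between 6.94% and 10.3% of the counts of a library, and in neither line did their list pass the list test (camera adjusted p = 0.246 in Huh7 and 0.464 in HCCLM3). It passed without Huh7 si-circASH2 replicate 2 (0.0394) or HCCLM3 si-circASH2 replicate 3 (0.0131). Markers of other cell types did not pass it either. Fibroblast markers gave camera adjusted p = 0.304 in Huh7 and 0.437 in HCCLM3, endothelial markers 0.884 and 0.191, and leukocyte markers 0.838 and 0.632.

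The gene count does not measure circASH2 itself, because no feature in the tables could be matched to the circle. ASH2L, the host gene on chromosome 8 (38105242 to 38144076, GRCh38) that encodes a subunit of the histone H3 lysine 4 methyltransferase complexes, was lower by a small amount in the si-circASH2 libraries of both lines. It fell from 76.5 ± 3.21 to 67.0 ± 1.33 CPM in Huh7, a log2 fold change of -0.19 ± 0.05 (edgeR adjusted p = 0.00304), and from 32.4 ± 1.59 to 27.5 ± 0.969 CPM in HCCLM3, a log2 fold change of -0.24 ± 0.05 (edgeR adjusted p = 0.0014). The fall of ASH2L does not show whether the circle was lowered, and its cause was not tested. ASH2L transcripts also hold TTATACCA in their coding sequence, a sequence described with the genes shared by the lines. TPM4, a tropomyosin that coats actin filaments and lies on chromosome 19 (16067021 to 16103005), was the gene the study is known for. Its level rose from 139 ± 5.69 to 374 ± 12.5 CPM in Huh7 and from 304 ± 6.69 to 617 ± 28.3 CPM in HCCLM3, log2 fold changes of 1.43 ± 0.04 (edgeR adjusted p = 9.39e-18) and 1.02 ± 0.04 (edgeR adjusted p = 6.16e-15). The rise was smaller in HCCLM3 by 0.40 (difference of the log2 fold changes -0.40 ± 0.05, edgeR adjusted p = 8.06e-06). In both lines all 3 si-circASH2 libraries lay above all 3 si-NC libraries for TPM4 and below them for ASH2L, which gives p = 0.1 in an exact two-sided permutation test, the smallest p that 20 arrangements of 3 against 3 libraries allow. The 3′ untranslated region (UTR) of TPM4 carries TCGGAGAA at 16101493 to 16101500, and genes with this sequence in their 3′ UTR rose as a group in both lines, as described with the genes shared by the lines.

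Other tropomyosins changed by less. TPM2 rose in Huh7 by 0.45 ± 0.04 on the log2 scale (edgeR adjusted p = 1.46e-08). In HCCLM3 its value was 0.09 ± 0.04 (edgeR adjusted p = 0.0916, 0.0326 without si-circASH2 replicate 1 and 0.0418 with each line fitted alone), and the difference between the lines passed the test (-0.36 ± 0.06, edgeR adjusted p = 7.25e-05). TPM3 was higher in both, by 0.16 ± 0.03 in Huh7 (edgeR adjusted p = 0.000373) and by 0.12 ± 0.03 in HCCLM3 (edgeR adjusted p = 0.00787, and 0.0617 without si-circASH2 replicate 1). TPM1 had a log2 fold change of 0.11 ± 0.06 in Huh7 (edgeR adjusted p = 0.155, and 0.0368 without si-circASH2 replicate 1) and of -0.18 ± 0.05 in HCCLM3 (edgeR adjusted p = 0.00905, 0.0523 without si-NC replicate 2 and 0.0524 without si-circASH2 replicate 3). YBX1, an RNA-binding protein of mRNA stability that the study is also known for, did not pass the test in either line, with -0.05 ± 0.03 in Huh7 (edgeR adjusted p = 0.204) and 0.07 ± 0.03 in HCCLM3 (edgeR adjusted p = 0.0682, and 0.0241 without si-circASH2 replicate 2). In HCCLM3 YBX1 passed with upper quartile factors in edgeR (adjusted p = 0.0375), with DESeq2 (0.0332) and with each line fitted alone (0.0383). With limma on the deposited FPKM the TPM3 calls of both lines were lost, at adjusted p between 0.0783 and 0.194, and over all genes above 0 so was that of TPM1 in HCCLM3 (0.0639).

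**Figure D1:**
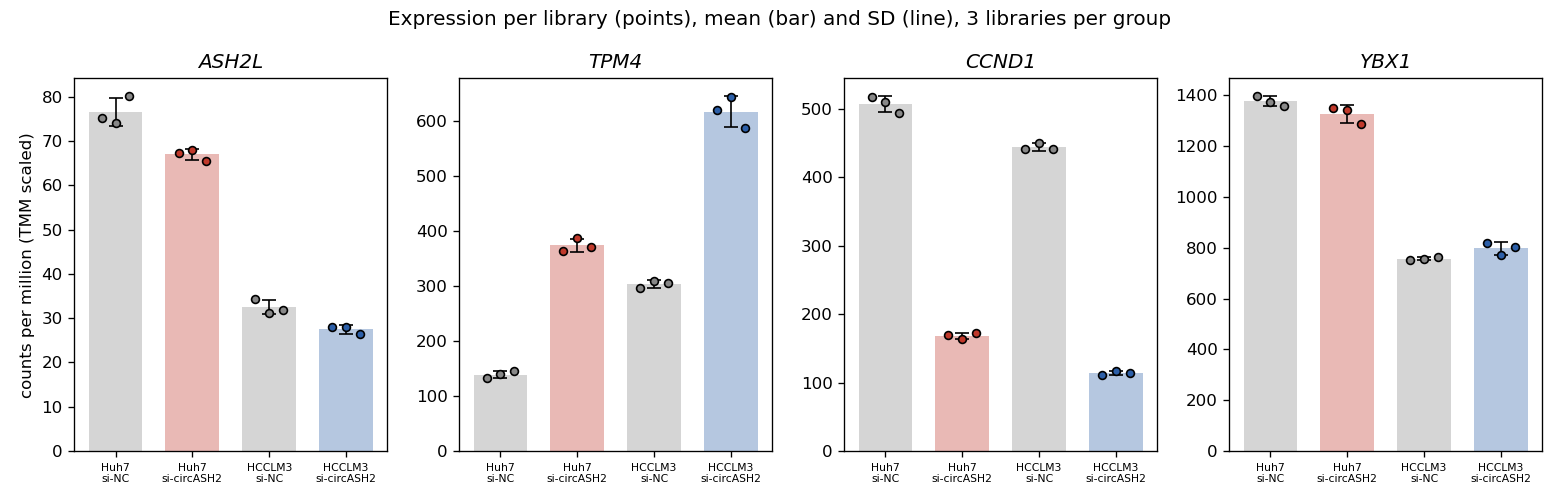
Expression of ASH2L, TPM4, CCND1 and YBX1 in CPM on a linear axis, with 1 point per library, bars for the mean and lines for the SD of the 3 libraries of each group (Huh7 and HCCLM3, si-NC and si-circASH2). TPM4 libraries of the si-circASH2 groups sit around 374 CPM in Huh7 and 617 CPM in HCCLM3 against 139 and 304 CPM in si-NC, while CCND1 lies around 168 and 114 CPM against 507 and 444 CPM.

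In Huh7, genes of the cell cycle and of lipid synthesis fell after si-circASH2. CCND1, which encodes cyclin D1 and drives entry into the cell cycle, fell from 507 ± 11.5 to 168 ± 4.09 CPM, a log2 fold change of -1.59 ± 0.03 (edgeR adjusted p = 6.28e-20). CDKN2B, an inhibitor of the kinases that cyclin D1 activates, rose from 24.2 ± 0.533 to 71.1 ± 0.763 CPM (1.56 ± 0.05, edgeR adjusted p = 2.08e-16). Among the genes that rose were AREG, a ligand of the EGF receptor (3.05 ± 0.632 to 13.9 ± 1.66 CPM, log2 fold change 2.19 ± 0.12), and CYR61, a secreted matricellular protein (15.7 ± 1.13 to 54.4 ± 4.42 CPM, 1.79 ± 0.07). PLA1A, a phospholipase, MYOF, a protein of membrane repair, FBN1, a structural protein of microfibrils, and RANBP3L rose by between 1.49 and 1.57 on the log2 scale. The largest fall among the genes named here by the rule on CPM and overlap was that of ARL2, a small GTPase involved in tubulin folding, from 28.2 ± 1.09 to 7.25 ± 0.422 CPM (-1.96 ± 0.08, edgeR adjusted p = 2.3e-14). RTN4, a reticulon of the endoplasmic reticulum, fell from 411 ± 11.3 to 164 ± 7.72 CPM (-1.33 ± 0.04). MICB, a stress-induced ligand of natural killer cells (-1.43 ± 0.07), GAL3ST1, an enzyme of sulfatide synthesis (-1.41 ± 0.17), ONECUT1, a hepatocyte transcription factor (-1.39 ± 0.14), IHH, a hedgehog ligand (-1.39 ± 0.17), and AFF3 (-1.34 ± 0.15) were also lower. CCND1, RTN4, MICB, GAL3ST1 and AFF3 carry in their 3′ UTR a copy of TTATACC or TATACCA, a pair of sequences described with the genes shared by the lines, and so does CYR61, which rose.

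The cell-cycle lists moved together in Huh7. Of the 34 genes of G2/M and mitosis 33 fell and 1 did not pass the test (33 adjusted over the list alone), with a median log2 fold change of -0.39 (camera adjusted p = 5.17e-26, and adjusted p = 0.00803 with an estimated correlation). The mitotic kinase gene CDK1 fell by 0.77 on the log2 scale, the transcription factor FOXM1 by 0.60, cyclin A2 (CCNA2) by 0.64 and the spindle kinesin KIF11 by 0.54. Of the 36 genes of DNA replication 34 fell and 2 did not pass (35 lower adjusted over the list alone), with a median of -0.38 (camera adjusted p = 2.62e-23, and adjusted p = 0.00803 with an estimated correlation). Here the ribonucleotide reductase subunit RRM2 fell by 0.56, the transcription factor E2F1, which carries 1 of the pair of sequences, by 0.81, the helicase subunit MCM7 by 0.43 and the sliding clamp PCNA by 0.51. Of 21 tested replicative histone genes 6 fell, 1 rose and 14 did not pass (6 and 1 adjusted over the list alone, median -0.47, camera adjusted p = 0.00692, adjusted p = 0.105 with an estimated correlation). HIST1H1C fell by 0.48 and HIST1H2AC by 0.47, while HIST1H2BD rose by 0.73 ± 0.14, and reads of such near-identical genes are uncertain.

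Lipid synthesis genes fell as well. Of the 25 genes of cholesterol synthesis 16 fell, 1 rose and 8 did not pass (19 and 1 adjusted over the list alone, median -0.24, camera adjusted p = 2.07e-07, adjusted p = 0.016 with an estimated correlation). NSDHL fell by 0.81 and carries 1 of the pair of sequences, and the sterol reductase DHCR7 fell by 0.32. Of 22 genes of fatty acid synthesis 14 fell, 1 rose and 7 did not pass (15 and 1 adjusted over the list alone, median -0.18, camera adjusted p = 8.14e-05, adjusted p = 0.016 with an estimated correlation). Fatty acid synthase (FASN) fell by 0.35 and the elongase ELOVL5 by 0.59, while malic enzyme ME1 rose by 0.35 ± 0.04.

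Lists of adhesion, matrix and signalling genes were higher in Huh7 by the test with a preset correlation, and none of their calls held with an estimated one. Among 21 targets of the Hippo effector YAP 10 rose, 1 fell and 10 did not pass (10 and 1 adjusted over the list alone, median 0.27, camera adjusted p = 4.74e-05, adjusted p = 0.0743 with an estimated correlation). CYR61, MYOF, ANKRD1 (1.23 ± 0.07) and CTGF (0.57 ± 0.05) were among those that rose. Of 39 actin cytoskeleton genes 19 rose, 3 fell and 17 did not pass (22 and 3 adjusted over the list alone, median 0.12, camera adjusted p = 7.7e-05, adjusted p = 0.133 with an estimated correlation). TPM4 and the membrane linker EZR (0.37 ± 0.03) rose, and ARPC5, a subunit of the actin-nucleating Arp2/3 complex whose 3′ UTR holds TTATACCA, fell by 0.82 (a call lost with limma on FPKM over all genes above 0, adjusted p = 0.0672). Among 23 mesenchymal genes 13 rose, 2 fell and 8 did not pass (13 and 2 adjusted over the list alone, median 0.29, camera adjusted p = 0.00853, adjusted p = 0.0635 with an estimated correlation). The intermediate filament vimentin (VIM) went from 68.4 ± 1.67 to 105 ± 8.81 CPM and the matrix protein SPARC from 27.5 ± 0.667 to 49.6 ± 0.879 CPM. Of 22 NF-kB and inflammation genes 9 rose, 2 fell and 11 did not pass (9 and 2 adjusted over the list alone, median 0.19, camera adjusted p = 0.00853, adjusted p = 0.296 with an estimated correlation). The chemokine CXCL5 was higher by 1.04 ± 0.08 and the chemokine CCL20 lower (-0.57 ± 0.05). Of 25 immediate early genes 12 rose, 2 fell and 11 did not pass (12 and 2 adjusted over the list alone, median 0.18, camera adjusted p = 0.00853, adjusted p = 0.0942 with an estimated correlation).

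Another 6 lists passed in Huh7. Targets of TGF-beta and SMAD (10 of 24 rose, 3 fell, 11 did not pass, median 0.05, camera adjusted p = 0.0347) included CDKN2B and TGFB1 (0.70 ± 0.05), and the call was lost with an estimated correlation (adjusted p = 0.279 with an estimated correlation), without si-circASH2 replicate 1 (camera adjusted p = 0.0825) and with a replicate block (0.0620). Of 26 focal adhesion and integrin genes 11 rose, 4 fell and 11 did not pass (median 0.07, camera adjusted p = 0.0384, adjusted p = 0.164 with an estimated correlation). The hyaluronan receptor CD44 went from 6.61 ± 0.683 to 13.8 ± 0.0845 CPM. The adhesion call was lost without si-NC replicate 1 (camera adjusted p = 0.0607), si-NC replicate 2 (0.0642) or si-circASH2 replicate 3 (0.0511). Of 26 matrix protease and inhibitor genes 11 rose and 15 did not pass (median 0.08, camera adjusted p = 0.0398, adjusted p = 0.112 with an estimated correlation). The protease call was lost without si-NC replicate 2 (camera adjusted p = 0.0885), si-circASH2 replicate 1 (0.0528) or si-circASH2 replicate 3 (0.0519), and with no filter on low counts (0.0610). For these 3 lists the numbers higher and lower adjusted over the list alone were 10 and 4, 11 and 4, and 11 and 0. Ribosomal protein genes (28 of 61 fell, 33 did not pass, 32 lower adjusted over the list alone, median -0.10, camera adjusted p = 2.07e-07, adjusted p = 0.347 with an estimated correlation) included RPS2 (-0.23 ± 0.03). Partners of YBX1 and genes of mRNA binding and decay (18 of 30 fell, 2 rose and 10 did not pass, 19 and 2 adjusted over the list alone, median -0.13, camera adjusted p = 0.000164, adjusted p = 0.0635 with an estimated correlation) were lower as a list. ZFP36L2 fell by 0.43, and G3BP2, which carries TCGGAGAA in its 3′ UTR, was higher by 0.73 ± 0.04. Liver targets of Wnt signalling (7 of 20 fell, 1 rose and 12 did not pass, 7 and 1 adjusted over the list alone, median -0.12, camera adjusted p = 0.0107, adjusted p = 0.156 with an estimated correlation) were lower as a list. Among them were CCND1, DKK1 (-0.58 ± 0.05) and LGR5 (-0.68 ± 0.09).

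By edgeR's quasi-likelihood test 5314 of 16946 genes passed an adjusted p of 0.05 in Huh7, 2761 higher and 2553 lower, with a median absolute log2 fold change of 0.30. In 7240 genes the libraries of the groups did not overlap, where chance gives 10% of genes. Requiring more than a 2-fold change left 326 genes, 252 higher and 74 lower. Of 33 lists 16 passed the list test and 4 of them held with an estimated correlation, and 9 other divisions of the same 6 libraries gave up to 14 lists.

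**Figure D2:**
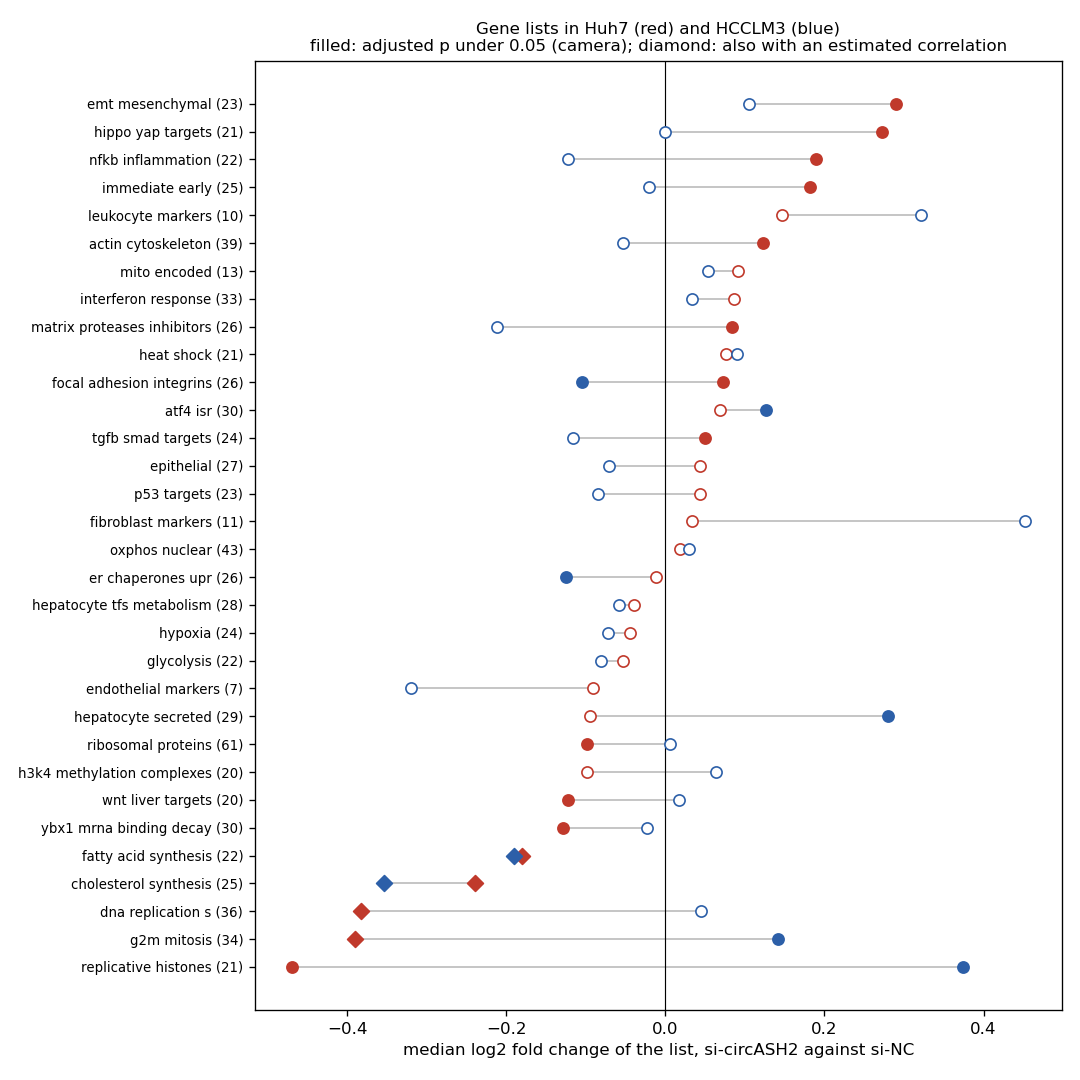
Median log2 fold change of the gene lists (tested members in brackets) in Huh7 (red) and HCCLM3 (blue), si-circASH2 against si-NC. Filled symbols passed camera's test with the preset correlation and diamonds also with an estimated one; G2/M and mitosis genes sit at -0.39 in Huh7 and 0.14 in HCCLM3, cholesterol synthesis at -0.24 and -0.35.

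In HCCLM3 CCND1 fell after si-circASH2 by more than any other named gene, genes of very different functions rose, and genes of sterol synthesis fell. CCND1 (chromosome 11, 69641087 to 69654474) fell from 444 ± 5.29 to 114 ± 2.87 CPM, a log2 fold change of -1.96 ± 0.03 (edgeR adjusted p = 8.94e-22). BIRC3, an inhibitor of apoptosis, fell from 81.9 ± 6.33 to 29.1 ± 0.851 CPM (-1.49 ± 0.07, edgeR adjusted p = 3.45e-13), and GNG12, a G protein subunit, had a log2 fold change of -1.59 ± 0.06 and 33.4 ± 2.83 CPM in the si-circASH2 libraries. GPNMB, a transmembrane glycoprotein, rose from 13.8 ± 1.53 to 52.5 ± 3.48 CPM (1.93 ± 0.08, edgeR adjusted p = 1.57e-14). Other genes that rose were CRYAB, a small heat shock protein (2.11 ± 0.20), CNTN6, a neural adhesion molecule (2.07 ± 0.24), BTC, a ligand of the EGF receptor (1.93 ± 0.23), MT2A, a metallothionein (1.52 ± 0.22), FAM167A (3.59 ± 0.181 to 10.2 ± 1.09 CPM), DNER (1.41 ± 0.24) and PRAP1 (1.38 ± 0.11). The surface glycoprotein CDCP1 (-1.80 ± 0.14), the glutamate transporter SLC1A7 (-1.59 ± 0.18), the tight junction protein CLDN2 (-1.58 ± 0.11), MICB (-1.57 ± 0.07) and GAL3ST1 (-1.53 ± 0.14) were lower. CCND1, CDCP1, GNG12, MICB and GAL3ST1 carry TTATACC or TATACCA in the 3′ UTR.

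Lipid synthesis genes fell in HCCLM3 too. Of the 25 cholesterol synthesis genes 20 fell and 5 did not pass (20 lower and 1 higher adjusted over the list alone), with a median of -0.35 (camera adjusted p = 6.65e-13, adjusted p = 0.00745 with an estimated correlation). The demethylase CYP51A1 fell by 0.60 on the log2 scale from 154 ± 5.96 CPM, squalene epoxidase (SQLE) from 275 ± 11.4 to 179 ± 3.35 CPM, and IDI1 and SC5D fell by 0.59 and by 0.55. Of 22 fatty acid synthesis genes 11 fell, 1 rose and 10 did not pass (13 and 1 adjusted over the list alone, median -0.19, camera adjusted p = 2.37e-06, adjusted p = 0.00745 with an estimated correlation). The desaturase FADS2 fell by 0.47, the elongases ELOVL5 and ELOVL6 by 0.43 and by 0.40, and LPIN1, a phosphatidate phosphatase that carries 1 of the pair of sequences, by 0.58. These were the 2 lists whose call held with an estimated correlation.

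Mitotic genes moved up in HCCLM3. Of the 34 genes of G2/M and mitosis 22 rose and 12 did not pass (22 higher and 2 lower adjusted over the list alone, median 0.14, camera adjusted p = 3.05e-07, adjusted p = 0.0971 with an estimated correlation). The kinetochore protein CENPF was higher by 0.50 ± 0.04, although its 3′ UTR holds 1 of the pair of sequences, the phosphatase CDC25B by 0.33 ± 0.03 and the spindle protein ASPM by 0.37 ± 0.04. Of 21 replicative histone genes 6 rose and 15 did not pass (6 higher adjusted over the list alone, median 0.37, camera adjusted p = 0.0259, adjusted p = 0.195 with an estimated correlation). The histone call was lost without si-circASH2 replicate 3 (camera adjusted p = 0.0584) and with no filter on low counts (0.0506). Of 36 DNA replication genes 9 rose, 6 fell and 21 did not pass (9 and 6 adjusted over the list alone, median 0.04, camera adjusted p = 0.209).

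Integrins and chaperones were lower and secreted liver proteins higher in HCCLM3. Of 26 focal adhesion and integrin genes 12 fell, 4 rose and 10 did not pass (14 and 4 adjusted over the list alone, camera adjusted p = 0.00583, adjusted p = 0.0971 with an estimated correlation). The median was -0.10 and the mean 0.08, which differ in sign. The collagen receptor subunit ITGA2 went from 351 ± 24.1 to 177 ± 10.4 CPM, ITGB1 fell by 0.42, and LIMS1, which carries TTATACCA in its 3′ UTR, by 0.62. Of 26 endoplasmic reticulum chaperone genes 14 fell, 1 rose and 11 did not pass (15 and 1 adjusted over the list alone, median -0.12, camera adjusted p = 0.00113, adjusted p = 0.0693 with an estimated correlation). XBP1 (-0.32 ± 0.04), whose 3′ UTR holds 1 of the pair of sequences, and HSP90B1 (-0.21 ± 0.03) were lower. Of 29 secreted hepatocyte proteins 11 rose, 1 fell and 17 did not pass (11 and 3 adjusted over the list alone, median 0.28, camera adjusted p = 0.0116, adjusted p = 0.0693 with an estimated correlation). The apolipoprotein APOA2 rose from 0.383 ± 0.109 to 4.77 ± 0.547 CPM (3.63 ± 0.15), against 1792 CPM in the si-NC libraries of Huh7, and APOH rose from 46.0 ± 1.99 to 75.9 ± 0.561 CPM. In the si-NC libraries the median log2 fold change of this list, HCCLM3 against Huh7, was -8.78, so calls of members with few counts in HCCLM3 are uncertain. Of 30 ATF4 and stress response genes 16 rose, 4 fell and 10 did not pass (17 and 5 adjusted over the list alone, camera adjusted p = 0.0146, adjusted p = 0.0971 with an estimated correlation). The median was 0.13 and the mean -0.02, which differ in sign. The alanyl-tRNA synthetase AARS was higher by 0.44 ± 0.03 and NUPR1 by 0.71 ± 0.09, while VLDLR, which carries 1 of the pair of sequences, was lower (-0.97 ± 0.09).

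By edgeR's quasi-likelihood test 5182 genes passed in HCCLM3, 2555 higher and 2627 lower, with a median absolute log2 fold change of 0.31. The libraries of the groups did not overlap in 7407 genes, against the 10% that chance gives. More than a 2-fold change was found in 368 genes, 206 higher and 162 lower. Of 33 lists 8 passed and 2 held with an estimated correlation, and other divisions of the 6 libraries gave up to 7 lists.

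CCND1 fell and TPM4 rose in both lines. Averaged over the lines, CCND1 had a log2 fold change of -1.78 ± 0.02 (edgeR adjusted p = 2.63e-24) and TPM4 of 1.22 ± 0.03 (edgeR adjusted p = 1.13e-19). Among the genes named for the average by the rule on CPM and overlap, larger rises than that of TPM4 were those of PPL, a desmosome-associated plakin (1.31 ± 0.10), the zinc finger gene ZNF616 (1.28 ± 0.07), and PLA1A (1.27 ± 0.07). Smaller ones were those of the actin cross-linker FLNC (1.12 ± 0.05) and CYR61 (1.06 ± 0.06). The metallothionein MT2A (1.02 ± 0.13) and the annexin ANXA1 also rose, ANXA1 from 13.8 ± 1.18 to 34.4 ± 4.49 CPM in Huh7 and from 424 ± 9.10 to 731 ± 24.0 CPM in HCCLM3. MICB fell from 33.3 ± 2.13 to 12.4 ± 0.163 CPM in Huh7 and from 27.4 ± 0.817 to 9.25 ± 0.423 CPM in HCCLM3. The others named by that rule for their average fall were GAL3ST1 (-1.47 ± 0.11), GNG12 (-1.37 ± 0.04), ARL2 (-1.24 ± 0.05), LRRC58 (-1.23 ± 0.03), RTN4 (-1.13 ± 0.03) and the Golgi mannosidase MAN2A1 (-1.09 ± 0.04).

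A fall of lipid synthesis genes was the change that the lists had in common. On average 21 of 25 cholesterol synthesis genes fell and 4 did not pass (21 lower adjusted over the list alone, median -0.29, camera adjusted p = 1.82e-12, adjusted p = 0.00614 with an estimated correlation). Of 22 fatty acid synthesis genes 15 fell on average, 1 rose and 6 did not pass (15 and 1 adjusted over the list alone, median -0.23, camera adjusted p = 1.03e-06, adjusted p = 0.00614 with an estimated correlation). The calls of the other 6 lists that passed were lost with an estimated correlation. The average falls of mitosis and DNA replication came from Huh7, since in HCCLM3 22 of 34 mitotic genes rose, and of 36 replication genes 9 rose and 6 fell. They were DNA replication (25 of 36 lower, 1 higher, 10 not past, adjusted p = 0.0834 with an estimated correlation), G2/M and mitosis (21 of 34 lower, 1 higher, 12 not past, adjusted p = 0.183 with an estimated correlation) and YAP targets (11 of 21 higher, 2 lower, 8 not past, adjusted p = 0.197 with an estimated correlation). The rest were ribosomal proteins (20 of 61 lower, 1 higher, 40 not past, adjusted p = 0.744 with an estimated correlation), partners of YBX1 with mRNA binding and decay (15 of 30 lower, 3 higher, 12 not past, adjusted p = 0.202 with an estimated correlation) and ATF4 with the stress response (15 of 30 higher, 4 lower, 11 not past, adjusted p = 0.183 with an estimated correlation). The numbers higher and lower adjusted over the list alone were, in that order, 1 and 25, 2 and 21, 11 and 2, 1 and 20, 4 and 17, and 17 and 4. The call for ribosomal proteins was also lost without Huh7 si-circASH2 replicate 3 (camera adjusted p = 0.0669). Wnt targets, at camera adjusted p = 0.1 for the average, passed without HCCLM3 si-NC replicate 2 (0.0353) and with no filter on low counts (0.0297), and mitochondrially encoded genes without HCCLM3 si-circASH2 replicate 3 (0.00868). With no filter on low counts mesenchymal genes and endoplasmic reticulum chaperones passed for the average as well (camera adjusted p = 0.0394).

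By edgeR's quasi-likelihood test 5957 genes passed for the average, 2991 higher and 2966 lower, and 275 of the calls were of more than 2-fold. Of the 5314 calls in Huh7 and 5182 in HCCLM3 a total of 2511 were shared. Of these 1924 (76.6%) had the same direction, 956 higher in both lines and 968 lower in both, where independent lists of these sizes would share 416 and 396. Opposite directions were found for 327 genes higher in Huh7 and lower in HCCLM3 and for 260 genes the other way, where independent lists would share 428 and 385. The lines share no libraries, but the dispersion of a gene was estimated over both, and independent lists take every gene as equally likely to be called. Across genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson correlation of 0.121 and a Spearman correlation of 0.212 over 16946 genes, and of 0.280 and 0.306 over the 12051 genes with at least 1 CPM in both lines. Of 33 lists 8 passed for the average and 2 held with an estimated correlation. At least 8 lists were given by 35 of 100 divisions of the libraries, but some of these kept 1 line as labelled and with it its effect. Divisions that kept neither line as labelled gave up to 12 lists, so the number of lists does not set the real division apart.

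**Figure D3:**
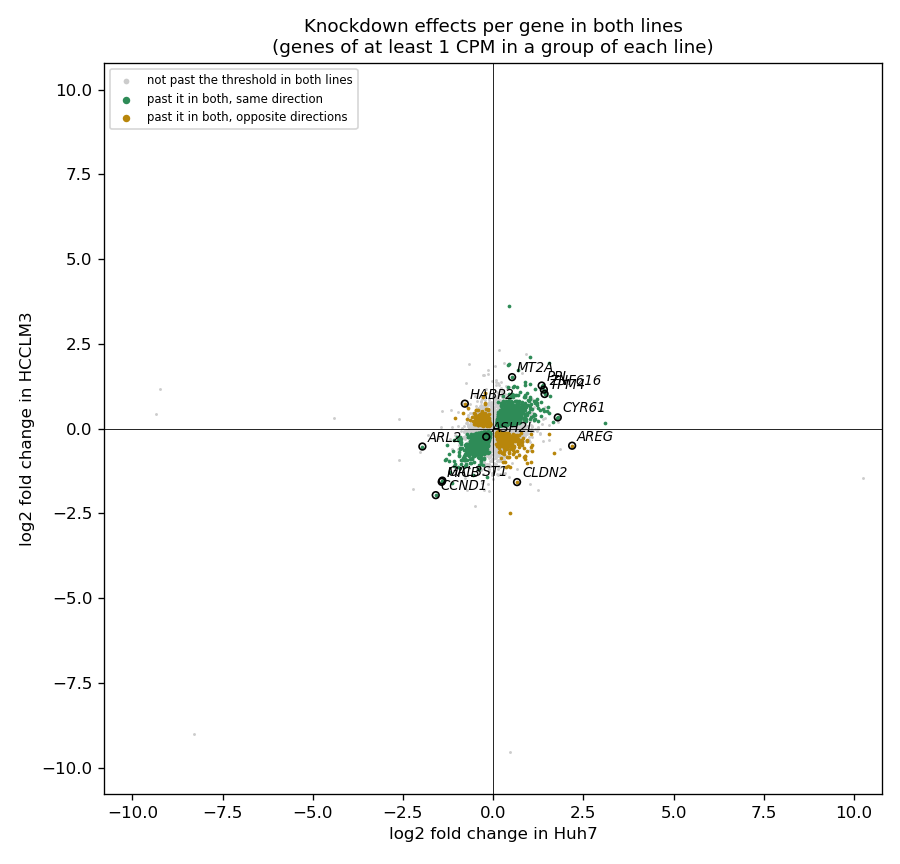
Log2 fold change (si-circASH2 against si-NC) in HCCLM3 against that in Huh7 for the 12051 genes with at least 1 CPM in both lines, 1 point per gene, with genes past the threshold in both lines coloured by whether the directions match. CCND1 lies at -1.59 and -1.96, TPM4 at 1.43 and 1.02, and AREG at 2.19 and -0.50.

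Genes that fell in both lines carried a short sequence in their 3′ UTRs more often than other genes. The 16187 sequences of 7 bases were scored on the fold changes of 10855 genes with an annotated 3′ UTR and at least 1 CPM. Fold changes were adjusted for the length and base composition of the 3′ UTR. Sequences were chosen on Huh7 and then scored on HCCLM3. The lowest score in Huh7 was that of TTATACC (-12.9), which scored -13.4 in HCCLM3, where the lowest score of any sequence in 100 permutations of the fold changes was -4.80. It overlaps TATACCA, the second lowest (-11.3 and -11.5). A copy of either was present in the 3′ UTR of 347 of 923 genes that fell in both lines (37.6%) and of 11.9% of the other genes. These shares rest in part on the Huh7 values that chose the sequences, and only the scores in HCCLM3 are independent of that choice. Unlike the scores, the shares are not adjusted for the length of the 3′ UTR. The 427 genes with the joined TTATACCA in the 3′ UTR had a median log2 fold change of -0.14 in Huh7 and -0.15 in HCCLM3, against 0.01 and 0.02 in 8538 genes with no copy in the 3′ UTR or coding sequence. Of the 8 genes named for their average fall 7 carry one of the pair, the exception being ARL2. Not all carriers fell: of the 1527 genes with either sequence in the 3′ UTR 347 fell and 64 rose in both lines. CYR61, which rose in both lines, CENPF, which rose in HCCLM3, and ITGAV and DUSP6, which rose in Huh7, are among the carriers.

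Genes that rose in both lines were richer in another sequence. CGGAGAA had the highest score in Huh7 (8.88) and scored 7.16 in HCCLM3, where the highest of 100 permutations was 4.95. In coding sequences its scores were 8.32 and 7.35, while TTATACC scored -5.83 and -8.08 there. CGGAGAA or the overlapping TCGGAGA was present in the 3′ UTR of 86 of 843 genes that rose in both lines (10.2%) and of 3.75% of the other genes. The same limits apply to these shares. The 65 genes with TCGGAGAA had a median log2 fold change of 0.18 in Huh7 and 0.15 in HCCLM3. Among them TPM4 ranked 1 in Huh7 and 3 in HCCLM3, and ZNF616 also carries a copy. Of other genes described in this text TPM3, ME1, HIST1H2BD, NUPR1 and TGM2 carry a 7-base part, and TGM2 fell in HCCLM3. TGM2 is not the only exception, since of all 461 genes with CGGAGAA or TCGGAGA in the 3′ UTR 86 rose and 24 fell in both lines.

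**Figure D4:**
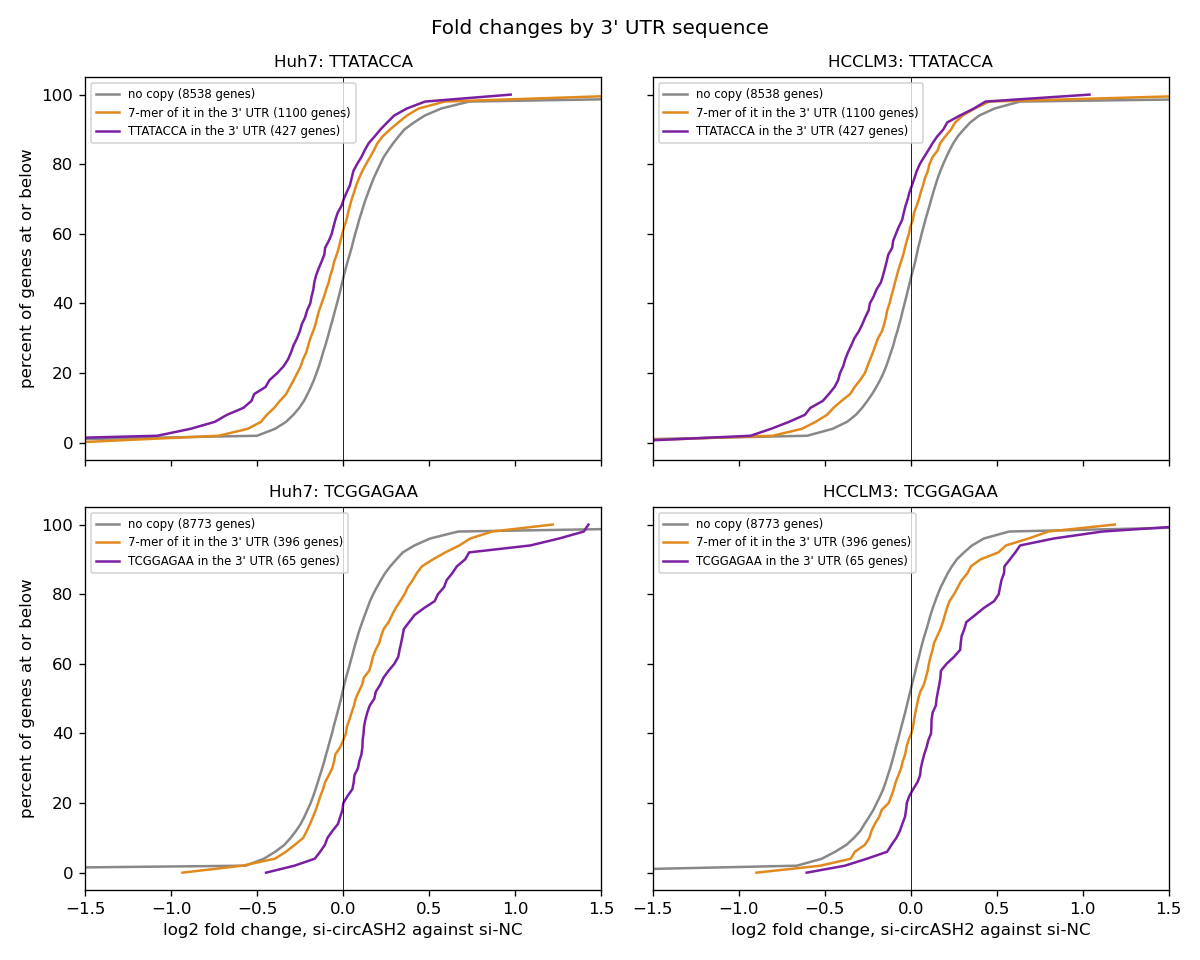
Cumulative percent of genes at or below a log2 fold change (si-circASH2 against si-NC) in Huh7 (left) and HCCLM3 (right), by the presence of TTATACCA (upper row) or TCGGAGAA (lower row) or a 7-base part of them in the 3′ UTR. Curves of the 427 genes with TTATACCA lie to the left of genes with no copy (medians -0.14 and -0.15) and those of the 65 genes with TCGGAGAA to the right (medians 0.18 and 0.15).

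The size of the response differed between the lines for genes of the cell cycle and of adhesion, by the test of the difference between their fold changes (HCCLM3 minus Huh7), and for some genes the direction did. AREG rose in Huh7 and fell from 31.5 ± 1.49 to 22.3 ± 0.766 CPM in HCCLM3, a difference of -2.69 ± 0.15 (edgeR adjusted p = 5.59e-12). CLDN2 likewise rose in Huh7 (0.66 ± 0.10) and fell in HCCLM3 (-1.58 ± 0.11), a difference of -2.24 ± 0.15 (edgeR adjusted p = 2.91e-10). The cell-cycle inhibitor CDKN1A rose from 14.9 ± 0.858 to 24.4 ± 1.16 CPM in Huh7 and fell from 126 ± 2.53 to 73.8 ± 5.52 CPM in HCCLM3 (-1.48 ± 0.08, edgeR adjusted p = 7.47e-12). ALS2CL (-1.69 ± 0.16), MYOF (-1.69 ± 0.07), the lipid droplet protein CIDEC (-1.59 ± 0.12), the protease-activated receptor F2RL1 (-1.55 ± 0.09) and the tetraspanin TSPAN8 (-1.48 ± 0.07) also rose in Huh7 and fell in HCCLM3. In the other direction the serine protease HABP2 fell in Huh7 (-0.78 ± 0.09) and rose in HCCLM3 (0.74 ± 0.09), a difference of 1.52 ± 0.13 (edgeR adjusted p = 8.43e-09). ARL2 fell in both lines, by 1.96 in Huh7 and by 0.53 in HCCLM3. PLXNC1, a semaphorin receptor (1.32 ± 0.16), SYNE2, a nuclear envelope protein (1.27 ± 0.09), SPTSSB, a subunit of serine palmitoyltransferase (1.21 ± 0.11), KLF2, a transcription factor (1.21 ± 0.12), ENPP2, which encodes autotaxin (1.19 ± 0.16), and PRAP1 (1.16 ± 0.15) had higher fold changes in HCCLM3.

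Cell-cycle lists differed between the lines. The difference was positive for all 34 genes of G2/M and mitosis, each past the test (34 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 3.26e-35, adjusted p = 0.00565 with an estimated correlation). It was 0.80 ± 0.06 for CENPF, 0.71 ± 0.06 for ASPM, 0.65 ± 0.05 for FOXM1 and 0.64 ± 0.05 for CDC25B. For DNA replication 33 of 36 genes were higher in HCCLM3 than in Huh7 by this measure and 3 did not pass (34 adjusted over the list alone, median 0.45, camera adjusted p = 6.9e-25, adjusted p = 0.00565 with an estimated correlation). MCM2 (0.70 ± 0.05) and PCNA (0.54 ± 0.05) were among them. Replicative histones gave 8 higher of 21 and 13 not past (11 adjusted over the list alone, median 0.88, camera adjusted p = 1.17e-05, adjusted p = 0.0234 with an estimated correlation). Of 34 histone genes on the list only 21 were tested, and reads of such near-identical genes are uncertain. The size of the histone median is therefore uncertain too.

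Adhesion and early response genes had lower fold changes in HCCLM3. Of 26 focal adhesion and integrin genes 14 had a lower fold change in HCCLM3, 1 a higher one and 11 did not pass (14 and 1 adjusted over the list alone, median -0.28, camera adjusted p = 1.17e-05, adjusted p = 0.0223 with an estimated correlation). ITGA2 rose in Huh7 (0.27 ± 0.06) and fell in HCCLM3 (-0.99 ± 0.05), and ITGAV, which carries 1 of the pair of sequences, did the same (0.33 ± 0.04 and -0.40 ± 0.04). Of 25 immediate early genes 11 had a lower fold change in HCCLM3, 1 a higher one and 13 did not pass (12 and 1 adjusted over the list alone, median -0.41, camera adjusted p = 0.000353, adjusted p = 0.0334 with an estimated correlation). DUSP6, a phosphatase of ERK with 1 of the pair of sequences (-0.87 ± 0.05), and EGR1 (-0.91 ± 0.10) were among them. Of 26 endoplasmic reticulum chaperone genes 9 were lower and 17 did not pass (12 lower adjusted over the list alone, median -0.10, camera adjusted p = 0.000533, adjusted p = 0.0419 with an estimated correlation). Of 29 secreted hepatocyte proteins 10 were higher, 1 lower and 18 did not pass (12 and 1 adjusted over the list alone, median 0.44, camera adjusted p = 0.000353, adjusted p = 0.0223 with an estimated correlation). The difference was 3.18 ± 0.16 for APOA2 and 0.82 ± 0.07 for APOH. Low counts of many members in HCCLM3 limit this call too.

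Another 10 lists passed with the preset correlation and were lost with an estimated one. Negative medians were those of NF-kB and inflammation (9 of 22 lower, 2 higher, adjusted p = 0.122 with an estimated correlation), TGF-beta and SMAD targets (10 of 24 lower, 2 higher, adjusted p = 0.0775 with an estimated correlation) and mesenchymal genes (8 of 23 lower, adjusted p = 0.0741 with an estimated correlation). Negative too were those of YAP targets (9 of 21 lower, 2 higher, adjusted p = 0.1 with an estimated correlation), matrix proteases (8 of 26 lower, 3 higher, adjusted p = 0.0506 with an estimated correlation), actin cytoskeleton (22 of 39 lower, 2 higher, adjusted p = 0.0775 with an estimated correlation) and cholesterol synthesis (11 of 25 lower, 2 higher, adjusted p = 0.0862 with an estimated correlation). Positive medians were those of ribosomal proteins (20 of 61 higher, adjusted p = 0.353 with an estimated correlation), H3 lysine 4 methylation complexes (6 of 20 higher, 1 lower, adjusted p = 0.0506 with an estimated correlation) and partners of YBX1 with mRNA binding and decay (7 of 30 higher, 3 lower, adjusted p = 0.128 with an estimated correlation). The numbers lower and higher adjusted over the list alone were, in that order, 10 and 3, 12 and 2, 8 and 0, 10 and 2, 12 and 4, 23 and 3, 11 and 2, 0 and 21, 1 and 6, and 3 and 7. ICAM1, a leukocyte adhesion receptor, rose in Huh7 (0.33 ± 0.04) and fell in HCCLM3 (-0.49 ± 0.04). So did the transglutaminase TGM2 (0.66 ± 0.06 and -0.33 ± 0.06) and the protease inhibitor TIMP1 (0.54 ± 0.05 and -0.23 ± 0.04). The lists of heat shock, hypoxia, glycolysis, oxidative phosphorylation, interferon response, p53 targets, epithelial genes and hepatocyte transcription factors and metabolism passed in none of the 4 tests of the knockdown, and the lowest of their camera adjusted p was 0.0599, for heat shock in the average. Heat shock genes passed the average test without HCCLM3 si-NC replicate 2 (camera adjusted p = 0.0439), HCCLM3 si-circASH2 replicate 3 (0.0461), Huh7 si-NC replicate 1 (0.0333) or 2 (0.0322), or Huh7 si-circASH2 replicate 1 (0.0270) or 3 (0.0279), and the HCCLM3 test without HCCLM3 si-NC replicate 2 (0.0438). They also passed, in HCCLM3 and for the average, with a replicate block (camera adjusted p = 0.0140 and 0.0236), with upper quartile factors (0.0402 and 0.0313) and with no filter on low counts (0.0455 and 0.0394).

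By edgeR's quasi-likelihood test the effect of the knockdown differed between the lines for 3538 genes, 1626 with a higher and 1912 with a lower fold change in HCCLM3, and 402 of the differences were of more than 2-fold. YBX1 was among them (0.13 ± 0.04, edgeR adjusted p = 0.0374), and its call was lost when any 1 of 8 libraries was left out, with edgeR adjusted p up to 0.140, with a filter of 5 CPM in 3 libraries (0.0502) and with limma on FPKM (0.0648 to 0.0766). The libraries were HCCLM3 si-NC replicate 1, 2 or 3, HCCLM3 si-circASH2 replicate 1 or 3, Huh7 si-NC replicate 1 or 2, or Huh7 si-circASH2 replicate 3.

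At baseline the lines differed in most genes. MSN, which encodes the membrane linker moesin, had 0 counts in all Huh7 libraries and 1197 ± 23.2 CPM in the si-NC libraries of HCCLM3, at least 36287-fold higher when Huh7 is set to 3 counts over the group. Likewise DHRS9, a retinol dehydrogenase, was at least 4157-fold higher in HCCLM3, MSC, a transcription factor, at least 3495-fold, and the matrix protease MMP7 at least 2966-fold, each with 0 counts in Huh7 si-NC. GPC3, a glypican of many liver cancers, stood at 1099 ± 26.3 CPM in Huh7 si-NC and at 0 counts in HCCLM3 si-NC, at least 32541-fold lower there. SERPING1, an inhibitor of complement C1, was at least 12395-fold lower, LIN28B, an RNA-binding protein, at least 10532-fold, and MASP1, a protease of the complement system, at least 9051-fold. SERPINA1, which encodes alpha-1 antitrypsin, had 3574 ± 121 CPM in Huh7 si-NC and 2 counts over the 3 libraries of HCCLM3 si-NC. All 29 secreted hepatocyte proteins were lower in HCCLM3 (29 adjusted over the list alone), among them AFP, the fetal albumin-like protein (9343 ± 106 against 3.35 ± 0.551 CPM), and APOB (8448 ± 77.0 against 52.0 ± 3.57 CPM). Hepatocyte transcription factors and metabolism gave 23 of 28 lower and 5 higher, and cholesterol synthesis 20 of 25 lower, 3 higher and 2 not past. Higher in HCCLM3 were 18 of 21 heat shock genes (3 lower), 17 of 26 focal adhesion and integrin genes (6 lower, 3 not past), and 17 of 26 matrix proteases and inhibitors (8 lower, 1 not past). CD44 stood at 324 ± 14.3 CPM in HCCLM3 against 6.61 ± 0.683 CPM in Huh7. TPM4 was higher in HCCLM3 (1.13 ± 0.04, edgeR adjusted p = 2.97e-18) and ASH2L lower (-1.24 ± 0.05, edgeR adjusted p = 5.09e-17). By edgeR's quasi-likelihood test 14445 of 16946 genes passed, 7056 higher and 7389 lower in HCCLM3, with a median absolute log2 fold change of 1.18, and the libraries of the groups did not overlap in 14663 genes, against the 10% that chance gives.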

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

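The divisions of the libraries counted for gene lists were tests chosen only after the result was seen, while the tests of the mitotic genes and the divisions counted for genes were chosen before. The results in this part were singled out because the effect of the knockdown differed between the lines in the test of the difference.

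The number of genes whose effect differed was 3538 by edgeR's quasi-likelihood test. Among the 100 divisions drawn no other gave as many, the highest being 1271 (1 of 100 divisions, the real one). Not drawn was the division that only exchanges the arms of HCCLM3, which turns the difference into the average (5957 genes). The other divisions drawn remove the knockdown effect of a line together with its difference from the other line, so they do not test that difference, which rests on the edgeR test alone. The highest counts came from divisions that kept 1 line as labelled (1271 with Huh7 and 1114 with HCCLM3), and the 82 divisions that kept neither gave at most 1 gene. Of 33 lists 17 passed by camera, with 18 in the highest other division (2 of 100 gave as many), and the same limit applies. Divisions that kept neither line as labelled gave up to 15 lists, those that kept Huh7 up to 16 and those that kept HCCLM3 up to 18.

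The median differences of these lists (HCCLM3 minus Huh7, log2) were 0.88 for replicative histones, whose reads are uncertain, 0.54 for G2/M and mitosis, 0.45 for DNA replication, 0.44 for secreted hepatocyte proteins, 0.15 for H3 lysine 4 methylation complexes, 0.13 for ribosomal proteins and 0.0748 for partners of YBX1. They were -0.47 for NF-kB and inflammation, -0.41 for immediate early genes, -0.28 for TGF-beta targets, for focal adhesion and for mesenchymal genes, -0.27 for YAP targets, -0.23 for matrix proteases, -0.20 for the actin cytoskeleton, -0.12 for cholesterol synthesis and -0.10 for endoplasmic reticulum chaperones.

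Differences of single genes were 1.52 for HABP2, 1.43 for ARL2, 1.32 for PLXNC1, 1.27 for SYNE2, 1.21 for KLF2 and for SPTSSB, 1.19 for ENPP2 and 1.16 for PRAP1. In the other direction they were -2.69 for AREG, -2.24 for CLDN2, -1.69 for ALS2CL and for MYOF, -1.59 for CIDEC, -1.55 for F2RL1, and -1.48 for CDKN1A and for TSPAN8. Among the genes named whatever their values they were -0.29 for TPM1, -0.36 for TPM2, -0.40 for TPM4 and 0.13 for YBX1. The call for TPM1 was lost with limma on FPKM (adjusted p = 0.133 to 0.179). Another 122 named genes also differed.

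Mitotic genes had a median log2 fold change of -0.39 in Huh7 and 0.14 in HCCLM3, and the difference was positive for 34 of 34 genes. Scaling is argued against as the source, because the median difference was still 0.530 with upper quartile factors and 0.54 with DESeq2 size factors. A few abundant genes taking most of the counts is argued against by a median difference of 0.552 without the 50 most abundant genes. A difference in culture density or harvest between the arms of 1 line may make all or part of the difference of 0.539. It cannot be told apart from the siRNA, since the labels give no culture or date. An effect of the siRNA that depends on the line may also account for the mitotic difference, and stays open as a hypothesis. Whether it would act through the circle or through seed matches cannot be told, since circASH2 was not measured.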

How the results depend on the processing

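Counting only genes with at least 1 CPM was a test chosen only after the results were seen. It gave 5134 genes in Huh7, 4995 in HCCLM3, 5537 for the average, 3305 for the interaction and 13127 at baseline. An absolute log2 fold change above 1 left, by its own construction as a stricter threshold, 326 genes in Huh7, 368 in HCCLM3, 275 for the average, 402 for the interaction, 8095 at baseline and 27 in the overlap. With an estimated correlation camera passed 4 lists in Huh7, 2 in HCCLM3, 2 for the average and 7 for the interaction, and fry, which tests each list without the other genes, passed 21 in HCCLM3 and 22 for the average. Without 1 replicate the genes numbered 4453 to 4822 in Huh7, 4281 to 4435 in HCCLM3, 5501 to 5763 for the average, 3047 to 3347 for the interaction, 14270 to 14318 at baseline and 1670 to 1785 in the overlap, and the lists 14 to 17, 8 to 9, 8 to 10, and 17 to 17. ASH2L then lay between -0.22 and -0.16 in Huh7 and between -0.26 and -0.20 in HCCLM3, and TPM4 between 1.40 and 1.46 and between 0.995 and 1.055. The replicate numbers were not taken to pair the libraries. Within the lines, correlations of libraries with the same number lay between -0.222 and 0.168, and those with different numbers between -0.195 and 0.184. Between the si-NC groups of the lines, those with the same number lay between 0.029 and 0.138, and those with different numbers between -0.174 and 0.089. Within the lines these values give no clear sign of pairing and do not exclude it. Between the lines replicates 1 (0.138) and 3 (0.111) lay above all pairs with different numbers, so an effect of the replicate number there stays open. With a replicate block 5349, 5215, 5927, 3533 and 14406 genes passed in the 5 comparisons, 1966 were shared, and 15, 9, 9 and 17 lists passed. With limma on FPKM the interaction of TPM3 was reversed (0.0260 with a pseudocount of 1, 0.0258 with 0.1, 0.0260 over all genes above 0), as was that of FBN1 (0.0229 with a pseudocount of 1 and 0.0229 over all genes above 0), and the cause was not tested. None of the reversed values passed (limma adjusted p = 0.861 to 0.898), and FBN1 was not reversed with a pseudocount of 0.1. Of the other values of named genes 5351 were the same, 8 stronger and 39 weaker. Depth limits what is said of genes near 3 counts over a group, between 0.0328 and 0.0338 CPM.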

Other observations

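The score tests of the 7-base sequences, the tests of near-silent genes and the divisions counted for genes were chosen before the results were seen, while the tests of genes without a copy, of TPM4, of the ASH2L exon, and the divisions counted for lists and for the overlap were tests chosen only after.

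Some members passed in lists that did not pass as a whole, where 31.4% of all genes passed in Huh7 and 30.6% in HCCLM3. Among 23 p53 targets 6 rose, 5 fell and 12 did not pass in Huh7, and 3 rose, 8 fell and 12 did not pass in HCCLM3. Of 33 interferon response genes 9 rose, 1 fell and 23 did not pass in Huh7, and 4 rose, 2 fell and 27 did not pass in HCCLM3. Of 24 hypoxia genes 1 rose, 3 fell and 20 did not pass in Huh7, and 1 rose, 4 fell and 19 did not pass in HCCLM3. Of 22 glycolysis genes 5 rose, 7 fell and 10 did not pass in Huh7, and 2 rose, 5 fell and 15 did not pass in HCCLM3. Among 43 nuclear genes of oxidative phosphorylation 4 rose, 5 fell and 34 did not pass in Huh7, and 9 rose, 3 fell and 31 did not pass in HCCLM3.

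The genes that fell in both lines, among them CCND1, may include direct seed matches of the siRNA of the si-circASH2 arm. The 7-base sequence with the lowest score in Huh7 scored -13.357 in HCCLM3, below the lowest of the permutations (-4.80) and below its score in coding sequences (-8.08). Whether seed matches account for all of them is open: among 8538 genes with no copy 483 fell in both lines where independent lists would share 259.9, a ratio of 1.859, but related sequences such as TATACCT also scored low in HCCLM3 (-7.58), and effects that follow from seed targets would be shared as well. For the genes that rose, a seed of the si-NC siRNA is open, because CGGAGAA scored 7.159 in 3′ UTRs of HCCLM3 and 7.35 in coding sequences, and 5.54 without genes that carry a coding copy, and here too genes with no copy (529 of 8773 against 266.4, a ratio of 1.986) were shared beyond independent lists. For TPM4, whose 3′ UTR carries the sequence, the score was 6.968 with TPM4 left out, so a rise of TPM4 by loss of a seed effect of the control siRNA cannot be told apart from an effect of the circle, since the labels name 1 treatment per arm and do not say how many siRNAs it held.

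A hypothesis on the origin of the first sequence was also looked at. TTATACCA lies in exon 6 of 16 of the transcript ASH2L-201 (chromosome 8, 38114196 to 38114203), 4 bases after the exon start, so a target of 19 bases ending in it would cross the exon junction. Of 65536 sequences of 8 bases 176 (0.269%) lie at such a place, and 5.20% anywhere in ASH2L transcripts. The place was defined after the sequence was seen there, so these shares do not decide whether an siRNA designed across a junction of the circle is its origin. The siRNA sequences would decide it.

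Calls were also made among genes close to silent in 1 line. Of 3093 such genes 249 passed in that line, and 29.3% of these calls (73 genes) stayed with each line fitted alone. Only 109 of the 249 were tested there, so most of the loss came from the filter on low counts. DESeq2 kept 217, but it too was fitted over both lines. Whether spread borrowed from the line that expresses the gene contributes is left open by these values. The summed level of 261 genes of HCCLM3 in Huh7 went from 24.8 to 36.5 CPM, a ratio of 1.47, between the values set beforehand for and against reads from the other line. Such reads as the source of this rise are argued against, because at the share needed the 10 most abundant HCCLM3 genes would gain 355.9 counts in the Huh7 si-circASH2 libraries, and they gained 61 (83 to 144). In HCCLM3 the summed level of 377 genes of Huh7 went from 38.3 to 42.3 CPM, a ratio of 1.11. There the 10 most abundant Huh7 genes went from 154 to 163 counts, where the share needed would add 157.2.

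Other divisions of the libraries were counted for the remaining results. For genes in Huh7 (5314, highest other 0), in HCCLM3 (5182, highest other 0) and at baseline (14445, highest other 0), and for lists in Huh7 (16, highest other 14) and in HCCLM3 (8, highest other 7), the 10 divisions, of which 1 reached the real value, are too few for a share under 0.05. For the average, 1 of 100 divisions gave 5957 genes (highest other 1271, from divisions that kept 1 line as labelled). A chance division of these libraries can therefore be excluded, in the sense that the libraries of the arms differed in at least 1 line. A chance difference between cultures cannot, since no label says that the 3 libraries of a group came from separate cultures. For lists in the average (8, highest other 17), 35 of 100 divisions gave as many, so chance cannot be excluded. The 17 lists came from a division that kept Huh7 as labelled, and divisions that kept neither line gave up to 12. For the overlap (1924, highest other 0), 1 of 100 divisions gave as many, but other divisions of a line called 0 genes, which fixes their overlap at 0, so this count tests nothing.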
